A study of Mus musculus with 6 samples.

How the data were processed

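Gene expression was measured with Affymetrix mouse expression arrays in the posterior part of the eye of mouse embryos at embryonic day 15.5. Per the labels' protocols, 6 dams were used, 3 of each genotype, and the eyes of 6 embryos of a dam were pooled into 1 sample, so a replicate is a litter pool. The anterior parts of the eyes had been cut away before RNA extraction, and biotinylated cRNA was made from 12.5 micrograms of total RNA, per the labels' protocols. The sexes of the embryos, the strain background and the extent of the deletion are not given in the sources used here.

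The deposited values are signal intensities on a linear scale, 1 per probe set and array, made by the authors with MAS5, per the submitters' processing notes. The version of MAS5 is not given in the sources used here. From the values themselves, each array had been scaled to a common target, since the mean after trimming 2% of the probe sets at each end was 500.002 on all 6 arrays. The deposited table was complete for 45101 probe sets, of which 64 were control probe sets. Detection calls were not used here, so a low intensity has no call of presence or absence beside it. The highest of the 27 bacterial control probe sets gave signals between 22.1 and 39.3 on the 6 arrays, and probe sets with means in that range lie near the background. The precision is limited by the number of arrays, 3 per genotype.

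Probe sets were named through the platform's annotation table, which gave 1 gene symbol for 34945 probe sets, several for 932 and none for 9160. A RefSeq gene table (assembly GRCm38.p6) was used to update symbols through Entrez identifiers and for the order of genes along the X chromosome. It matched 34754 of the symbols and changed 0 of them. No gene was named from a probe set with several symbols.

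The computed values were log2(signal + 16), with no further normalization. Control probe sets were left out of the tests, and probe sets whose mean over the 6 arrays lay above the 40th percentile were kept, which left 27029 probe sets of 12902 genes. A linear model was fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), the Oa1-/- group minus the WT group, with no covariate. Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets kept and a threshold of 0.05. Fold changes are on the log2(signal + 16) scale, which understates the change of dim probe sets.

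Gene lists were tested with limma's camera with a preset correlation between genes of 0.01, on 1 probe set per gene, the brightest over the 6 arrays. Of 29 lists, 28 had at least 5 measured genes and were tested, with Benjamini-Hochberg adjustment over those 28. Beside it, camera was run with a correlation estimated for each list, and fry tested whether a list's genes moved one way on balance. The lists cover pigment synthesis and melanosome structure, lysosome-related organelle biogenesis, lysosome, heterotrimeric G proteins, tyrosine and dopamine metabolism, cell cycle, cyclin D and CDK inhibitors, axon guidance, stress, metabolic and ribosomal genes, and markers of the retina, the pigment epithelium, lens, surface epithelium, muscle, cartilage, mesenchyme, blood, endothelium, macrophages and melanocytes. Single values were compared with exact permutation tests, which cannot give a two-sided p below 0.1 with 3 samples against 3.

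The lists, the model, the thresholds, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took the targeted gene, then probe sets past the threshold whose groups did not overlap. Where fewer than 12 in a direction passed, it filled that direction to 8 by the smallest unadjusted p among probe sets with 1 symbol and no overlap of the groups. It added up to 4 members with the smallest unadjusted p from each list past the threshold, and from the pigment, pigment epithelium and G protein lists in any case. The sex-linked genes were the last part.

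The code was tested on simulated data made from the 27029 probe sets, in which sets of 50 were changed by a known amount. Over 20 draws, an average of 11.5% of probe sets with a log2 change of 0.5 were called at an adjusted p below 0.05, 65.2% with a change of 1, 90.0% with a change of 2 and 70.2% with a change of 3. On average 7.14% of the calls were false, and in a single draw with no change simulated 0 were called. All sizes of change were simulated together, on the same probe sets in every draw. The noise was drawn independently for each probe set. Variation shared between probe sets was not simulated, so these shares test the code and do not carry over to the real arrays.

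Alternatives were other pseudocounts (1 and 64), no filter and a filter at the 70th percentile, quantile normalization, median centring, other variance settings, array weights, the replicate number as a block, probe sets of 1 transcript group, the mean of a gene's probe sets, and leaving out each array in turn. A covariate for Y-linked signal, and leaving out both arrays that stood apart, were added after the data had been examined.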

Results

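The data set compared the embryonic eye of mice lacking Oa1, now named Gpr143, with that of wild-type (WT) mice. Gpr143 encodes a G protein-coupled receptor of pigment cells that sits in the membranes of melanosomes and endolysosomes, and its loss causes ocular albinism. RNA from the posterior eye was measured at embryonic day 15.5, when retinal ganglion cells are being made and the pigment epithelium is pigmented. There were 3 WT and 3 Oa1-/- arrays, each from a pool of 6 embryos of 1 dam. The median signal of the WT arrays was 117, 121 and 108, and that of the Oa1-/- arrays was 93.6, 118 and 129. Signals ran from 0.0385 to 30680. The first principal component held 46.4% of the variance and was led by Oa1-/- replicate 1. The second held 18.7% and was led by WT replicate 3, so neither followed the genotype.

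The targeted gene was measured first. Gpr143 had 1 probe set (1420581_at), with a signal of 251 ± 5.30 (SD, n = 3) in WT and 24.5 ± 16.9 (SD, n = 3) in Oa1-/-. The Oa1-/- arrays read 28.3, 39.1 and 6.02, within or below the range of the highest bacterial controls over all arrays. Each lay far under the lowest WT value of 246. The highest bacterial control on the same arrays read 22.1, 26.5 and 39.3, so Oa1-/- replicates 1 and 2 lay above theirs. The log2 change was −2.82 (SE 0.33), a 7.07-fold difference on the log2(signal + 16) scale. It had an unadjusted p of 2.12e-05 and an adjusted p of 0.287 in limma, so it did not pass the threshold over all probe sets. The groups did not overlap, and the exact permutation p was 0.1, the smallest that 3 against 3 can give. All 6 arrays followed their labels, as far as this probe set lies in the part of the gene that was removed, which is not given in the sources used here.

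The sex-linked genes set 1 WT array apart. Eif2s3y, Kdm5d and Uty, which lie on the Y chromosome, gave signals of 9.26, 13.5 and 14.4 on WT replicate 3, while the lowest values on the other 5 arrays were 406, 377 and 189. Xist, the RNA that coats the inactive X chromosome of female cells, was highest on that array on 3 of its 3 tested probe sets. The Oa1-/- minus WT log2 change was 1.65 for Eif2s3y, 1.51 for Kdm5d, 0.99 for Uty and −0.45 for the brightest Xist probe set (1436936_s_at), with an adjusted p of 0.985 for each in limma. Another Xist probe set, 1427262_at, read 1376 ± 675 in WT and 388 ± 90.2 in Oa1-/- (log2 change −1.68, unadjusted limma p 0.00112), and 1427263_at read 2337 and 1679. Leaving out WT replicate 3 took the change of Eif2s3y to 0.17, that of Kdm5d to 0.13 and that of Uty to 0.01, and leaving out Oa1-/- replicate 2 took that of Xist to −0.25. Without WT replicate 1 the changes of Eif2s3y, Kdm5d and Uty were 2.56, 2.31 and 1.57.

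**Figure D1:**
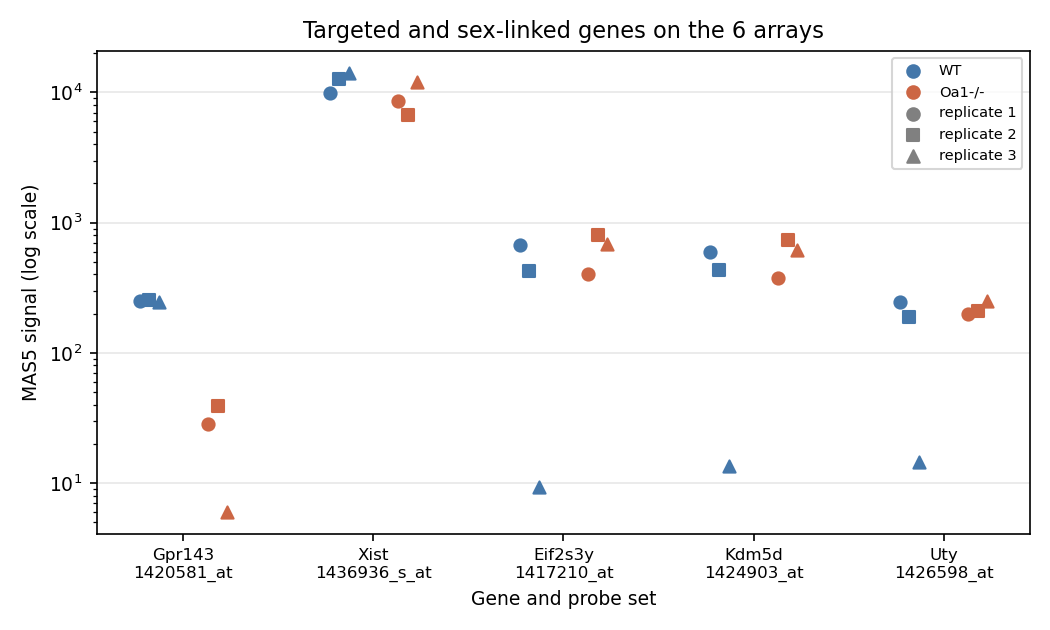
MAS5 signal on a log scale for 1 probe set of Gpr143, Xist, Eif2s3y, Kdm5d and Uty, 1 point per array, with colour for the genotype and shape for the replicate. Gpr143 lies between 246 and 257 on the WT arrays and at or below 39.1 on the Oa1-/- arrays, and WT replicate 3 lies at or below 14.4 for the 3 Y-linked genes.

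Across the eye transcriptome, no probe set passed the threshold. In limma, 0 of 27029 probe sets had an adjusted p below 0.05 and 0 below 0.10, and the smallest adjusted p was 0.234. At an unadjusted p below 0.05 there were 1111 probe sets, 449 higher and 662 lower in Oa1-/-, where chance alone gives 1351. The lean to lower values depended on the scaling and on single arrays, with 589 higher and 622 lower after quantile normalization, 585 and 593 without Oa1-/- replicate 1, and 361 and 873 without Oa1-/- replicate 3. At an unadjusted p below 0.01 there were 211, where chance gives 270. Of the 1111, 258 differed by at least 1.5-fold, 99 higher and 159 lower. The groups did not overlap for 10.2% of probe sets, against 10% by chance. With median centring or with array weights 2 probe sets passed, Kantr in both cases, with Gpr143 in the first and Slc25a29 in the second.

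The 8 genes with the smallest p among those with a higher signal in Oa1-/- did not pass the threshold. Nnat, an imprinted gene encoding the membrane proteolipid neuronatin, came first, at 2952 ± 336 in WT and 4776 ± 146 in Oa1-/- (SD, n = 3), a log2 change of 0.70 (SE 0.09, adjusted p = 0.362 in limma). Lmo1, a LIM-only transcriptional regulator, had a log2 change of 0.60, and Ncan, the extracellular matrix proteoglycan neurocan, one of 0.57. Dnase2a, a lysosomal nuclease, had a log2 change of 0.76, Dda1 0.67, Mrps5, of the mitochondrial ribosome, 0.62, Rimklb 0.58 and Fam126b 0.45. These 7 had an adjusted p of 0.985. Other probe sets of a gene did not always share the sign. The brightest probe set of Dda1 read 2491 in WT and 2310 in Oa1-/-, that of Mrps5 865 and 786 (with another at 326 and 444), and that of Rimklb 2120 and 1893. Of the 3 other probe sets of Fam126b, 0 had a higher mean in Oa1-/-.

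Among the genes with a lower signal, Kantr, a long noncoding RNA gene on the X chromosome, had the smallest p of all. Its probe set 1438575_a_at read 213 ± 48.2 in WT and 23.6 ± 9.92 in Oa1-/- (SD, n = 3), a log2 change of −2.54 (SE 0.27, adjusted p = 0.234 in limma), which ran from −3.18 with a pseudocount of 1 to −1.65 with a pseudocount of 64. Without WT replicate 1 or without WT replicate 3, 1438575_a_at fell under the filter and was not tested. The Oa1-/- value lies near the background, and another Kantr probe set, 1428499_at, read 433 and 439. A dimmer Kantr probe set that did not pass the filter read 73.0 and 24.6. Slc25a29, a mitochondrial carrier of basic amino acids, read 156 ± 12.7 and 38.1 ± 10.3 on 1423981_x_at (log2 change −1.69, adjusted p = 0.362), while its brightest probe set read 394 and 398. The Oa1-/- value again lies near the background, and the change ran from −2.04 to −1.11 over the alternatives. Erdr1 read 10388 ± 1051 and 5210 ± 1135 (log2 change −1.01, adjusted p = 0.753). Dcx, encoding the microtubule-binding protein doublecortin of young neurons, read 855 ± 204 and 346 ± 69.6 on 1418141_at (log2 change −1.25, adjusted p = 0.838), but 2039 and 2482 on 1418139_at.

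The remaining genes in this direction changed less. Peg3, an imprinted zinc finger gene, read 4154 ± 23.6 and 3127 ± 25.0 (log2 change −0.41, adjusted p = 0.838), while its brightest probe set read 8923 and 8692. Dnmt3a, a de novo DNA methyltransferase, had a log2 change of −0.52 (adjusted p = 0.838). Its probe sets 1423065_at and 1423066_at read 1584 and 1667 in WT and 1102 and 1168 in Oa1-/-, and its brightest probe set read 2688 and 2527. Tfap2b, a transcription factor of neural crest and amacrine cells, had a log2 change of −0.53 (adjusted p = 0.985), and both of its probe sets had a lower mean in Oa1-/-.

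**Figure D2:**
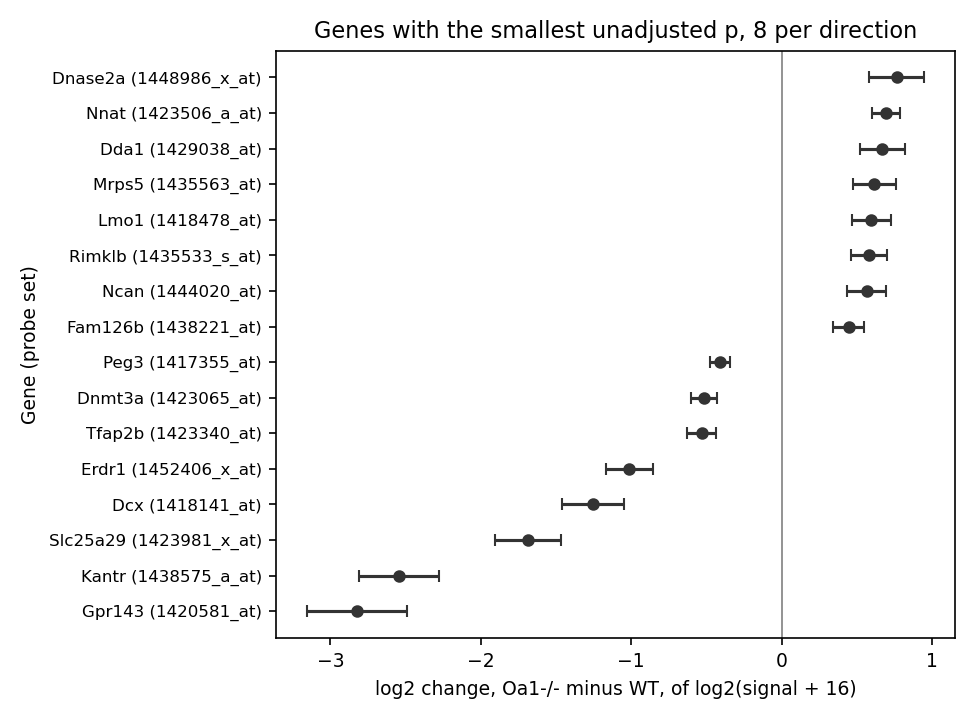
Log2 change, Oa1-/- minus WT, of log2(signal + 16) for the 8 genes per direction with the smallest unadjusted p, with bars of 1 SE. The changes run from −2.82 for Gpr143 to 0.76 for Dnase2a, and none of the 16 passed an adjusted p of 0.05.

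Markers of the periocular mesenchyme, the neural crest-derived tissue around the optic cup, were lower as a list in Oa1-/-. Of 31 measured genes, 26 had a negative and 5 a positive log2 change, with a mean of −0.15 and a camera adjusted p of 8.38e-05. The adjusted p was 0.604 with an estimated correlation, so the call rests on the preset one. The exact permutation p of the list's mean score was 0.1, with all 3 Oa1-/- arrays below all 3 WT arrays. The 3' and 5' control probe sets for 18S ribosomal RNA separated the genotypes too, at 1817 and 2838 in WT and 3858 and 7285 in Oa1-/-. Of its members, 5 had an unadjusted p below 0.05, all lower, and 0 passed when adjusted over all probe sets or adjusted over the list alone. Fbln2, the matrix protein fibulin 2, read 1338 ± 127 in WT and 1008 ± 75.8 in Oa1-/- (log2 change −0.40). Fap, a fibroblast surface protease, had a log2 change of −0.34, the transcription factor Osr1 one of −0.76 and Tfap2b (1435670_at) one of −0.22. Without WT replicate 3 the change of Osr1 was −0.51. Tfap2b is also in the amacrine and horizontal cell list.

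Genes of oxidative phosphorylation were higher as a list. Of 46 measured genes, 40 had a positive and 6 a negative log2 change, with a mean of 0.07 and a camera adjusted p of 0.00152. The adjusted p was 0.916 with an estimated correlation. Sdhd, a subunit of succinate dehydrogenase, had a log2 change of 0.27, the complex I subunits Ndufa5 and Ndufb5 had 0.20 and 0.19, and the ATP synthase subunit Atp5h had 0.13. Another Ndufa5 probe set, 1417285_a_at, read 2060 in WT and 2073 in Oa1-/-, while the other probe sets of Sdhd, Ndufb5 and Atp5h were higher too. Without Oa1-/- replicate 1 the change of Ndufb5 was 0.09. 2 members had an unadjusted p below 0.05, and 0 passed over all probe sets or adjusted over the list alone. The list's score was highest on Oa1-/- replicate 1, the array with the highest 18S ribosomal RNA control signals. The call ended without WT replicate 1 (mean 0.03, adjusted p = 0.151), without Oa1-/- replicate 1 (mean 0.02, adjusted p = 0.620), and with quantile normalization (mean 0.04, 0.118) or median centring (mean 0.10, 0.0614). The mean was 0.11 without WT replicate 3 and 0.11 without Oa1-/- replicate 3.

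Retinal ganglion cell markers were also higher as a list. Of 33 measured genes, 24 had a positive and 9 a negative log2 change, with a mean of 0.08 and a camera adjusted p of 0.0101, and the adjusted p was 0.916 with an estimated correlation. Stmn2, a regulator of microtubules in growing axons, read 6833 ± 785 in WT and 8443 ± 397 in Oa1-/- (log2 change 0.31). Sncg, gamma-synuclein, had a log2 change of 0.36, Dcx (1418139_at) one of 0.29 and Gap43, a growth cone protein, one of 0.27. Another Dcx probe set, 1418141_at, had a log2 change of −1.25, while the other Stmn2 probe set had one of 0.25. Without WT replicate 1 the change of Sncg was 0.22, and without Oa1-/- replicate 1 that of Gap43 was 0.18. 5 members had an unadjusted p below 0.05, all higher, and 0 passed over all probe sets or adjusted over the list alone. The call ended without WT replicate 1, whose score was the lowest of the 6 arrays and without which the mean was 0.02 (adjusted p = 0.124), while the mean was 0.14 without WT replicate 3. It also ended with no filter (mean 0.07, adjusted p = 0.0585), quantile normalization (mean 0.07, 0.0570), median centring (mean 0.11, 0.0614) or the mean of a gene's probe sets (mean 0.05, 0.142).

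Immediate early and stress response genes were lower as a list. Of 27 measured genes, 18 had a negative and 9 a positive log2 change, with a mean of −0.11 and a camera adjusted p of 0.0101, and the adjusted p was 0.916 with an estimated correlation. Jund, a member of the AP-1 family, had a log2 change of −0.28, the heat shock gene Hspa1a one of −0.46, the matricellular gene Ccn1 one of −0.29 and Klf4 one of −0.25. Without WT replicate 1 the change of Ccn1 was −0.19. 2 members had an unadjusted p below 0.05, and 0 passed over all probe sets or adjusted over the list alone. The call ended without WT replicate 3 (mean −0.07, adjusted p = 0.223), without Oa1-/- replicate 3 (mean −0.06, adjusted p = 0.366), with the Y-linked covariate (0.336), with a filter at the 70th percentile (0.243) and with array weights (0.245). None of the 4 list calls held with an estimated correlation.

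**Figure D3:**
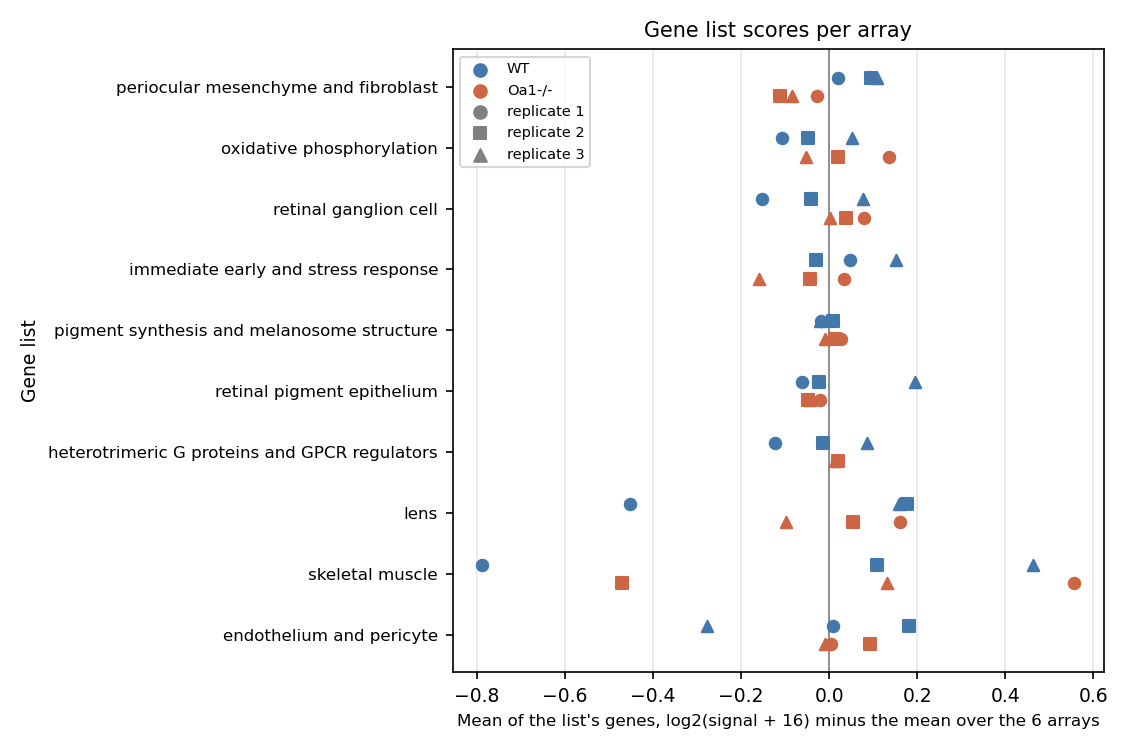
Mean score of 10 gene lists on each array, as log2(signal + 16) minus the mean over the 6 arrays, averaged over the list's genes, with colour for the genotype and shape for the replicate. The genotypes separate for the mesenchyme list (WT 0.02 to 0.11, Oa1-/- −0.11 to −0.03), and WT replicate 1 is lowest for the lens (−0.45) and skeletal muscle (−0.79) lists.

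The lists closest to the function of Gpr143 did not pass. Of 24 measured genes of pigment synthesis and melanosome structure, 13 had a positive and 11 a negative log2 change, with a mean of 0.02 (camera adjusted p = 0.787) and 0 with an unadjusted p below 0.05. With 1 array left out the mean ran from 0.00302 (without Oa1-/- replicate 1) to 0.03 (without WT replicate 2). Tpcn2, an endolysosomal ion channel, had a log2 change of −0.36, Rab27a, which moves melanosomes, one of −0.19, the melanocortin receptor Mc1r one of 0.37 and the channel Trpm1 one of −0.13. Without Oa1-/- replicate 1 the change of Tpcn2 was −0.18 and that of Trpm1 −0.21, and without Oa1-/- replicate 3 that of Trpm1 was −0.08. The pigment epithelium list had 7 positive and 15 negative of 22 genes, with a mean of −0.07 (adjusted p = 0.205). Ttr, transthyretin, had a log2 change of −0.44, Krt8 −0.38, Ezr −0.16 and the retinol dehydrogenase Rdh10 0.11. Its score was highest on WT replicate 3, and without that array the mean was 0.00459 (adjusted p = 0.999), so the negative mean rested on 1 array. Without WT replicate 1 the list passed, at a mean of −0.12 (adjusted p = 0.0189). Without WT replicate 3 the change of Ttr was −0.26, that of Krt8 −0.12 and that of Rdh10 0.07. With 1 array left out Ttr ran from −0.70 to −0.26, Krt8 from −0.63 to −0.12, Ezr from −0.23 to −0.08 (without WT replicate 2) and Rdh10 from 0.07 to 0.21.

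The list of heterotrimeric G proteins and receptor regulators had 25 positive and 18 negative of 43 genes, with a mean of 0.03 (adjusted p = 0.787). The receptor kinase Grk6 had a log2 change of −0.19 and the only unadjusted p below 0.05 in this list, Gpsm1 had −0.18, the adenylyl cyclase Adcy6 −0.30 and Gng3 0.18. Without Oa1-/- replicate 1 the change of Adcy6 was −0.10 and that of Gng3 0.11. The list's mean was −0.02 without WT replicate 1 and 0.09 without WT replicate 3, not past the threshold in either case. Lysosome genes (mean −0.01, adjusted p = 0.800), genes of lysosome-related organelle biogenesis (mean −0.00498, median 0.00672, adjusted p = 0.949) and of tyrosine and dopamine metabolism (mean 0.03, adjusted p = 0.518) did not pass either. With 1 array left out these means turned sign. They ran from −0.05 (without Oa1-/- replicate 1) to 0.03 (without WT replicate 3) for lysosome genes, and for the other lists from −0.03 to 0.02 and from −0.02 to 0.09 (both without WT replicate 1 and without WT replicate 3). In each of the 28 lists tested, 0 genes passed when adjusted over all probe sets or adjusted over the list alone.

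Other retinal cell types gave no call in the main fit. Retinal progenitor markers had a mean log2 change of 0.04 (adjusted p = 0.321), photoreceptor precursor markers 0.10 (0.205), cell cycle genes −0.01 (0.800), cyclin D and CDK inhibitor genes 0.03 (0.787), and astrocyte and optic nerve head markers 0.02 (0.800). Amacrine and horizontal cell markers had a mean of −0.01 and a median of 0.02 (0.787), and axon guidance genes a mean of 0.03 and a median of −0.02 (0.787). With 1 array left out, means ran from −0.12 to 0.09 for amacrine and horizontal cells, −0.04 to 0.10 for astrocytes (both without WT replicate 1 and without WT replicate 3), −0.02 to 0.07 for cyclin D and CDK inhibitors (the same arrays), −0.03 (without WT replicate 2) to 0.01 (without Oa1-/- replicate 3) for the cell cycle and −0.00328 (without Oa1-/- replicate 3) to 0.07 (without Oa1-/- replicate 1) for axon guidance, and none passed. Without WT replicate 3 the photoreceptor precursor list passed, at a mean of 0.25 (adjusted p = 8.41e-05), but without WT replicate 1 its mean was −0.03 (0.593). That list also passed with the Y-linked covariate (mean 0.27, 2.20e-05) and without both arrays that stood apart (mean 0.26, 0.000197). With an estimated correlation in the main fit its camera adjusted p was 0.916. The progenitor list's mean was 0.00473 without WT replicate 2, and with array weights that list passed, at a mean of 0.09 (adjusted p = 0.00518).

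The other markers of tissues outside the retina gave no call in the main fit. In other fits of all 6 arrays some passed camera with the preset correlation. With median centring these were surface epithelium at −0.09 (adjusted p = 0.0178) and muscle at 0.18 (0.0133). With the Y-linked covariate they were lens at 0.21 (2.43e-05) and muscle at 0.50 (1.11e-07), and with array weights muscle at −0.28 (0.00184). Lens markers had a mean log2 change of 0.08 (adjusted p = 0.194) and skeletal muscle markers one of 0.14 (adjusted p = 0.205), and WT replicate 1 was lowest for both. Without that array the lens list passed at −0.13 (adjusted p = 0.000449) and the muscle list at −0.21 (adjusted p = 0.00767), in the other direction. The muscle list passed at 0.23 without WT replicate 2 (adjusted p = 0.0402), at 0.41 without WT replicate 3 (3.60e-05) and at 0.42 without Oa1-/- replicate 2 (1.48e-06). The lens list passed at 0.19 without WT replicate 2 (0.00115), at 0.18 without WT replicate 3 (0.000603) and at 0.15 without Oa1-/- replicate 3 (0.0202). All calls with an array left out used the preset correlation. With all 6 arrays the correlation between genes was estimated at 0.770 for muscle and 0.766 for lens, and camera then gave unadjusted p values of 0.701 and 0.667. Means were −0.12 for surface epithelium (adjusted p = 0.119), −0.09 for cartilage and sclera (0.194), 0.06 for endothelium and pericytes (0.515), −0.03 for macrophages and microglia (0.583) and 0.02 for melanocytes and neural crest (0.949). Erythrocyte genes had a mean of 0.02 and a median of −0.02 (0.954). Unfolded protein response genes had a mean of 0.03 (0.656), hypoxia and glycolysis genes −0.05 (0.304) and cytosolic ribosomal protein genes 0.04 (0.194). Without WT replicate 1 the surface epithelium list passed at −0.31 (adjusted p = 1.41e-06) and the cartilage list at −0.15 (0.0170), but without WT replicate 3 their means were −0.00102 (0.449) and −0.04 (0.374). Without WT replicate 2 the endothelium list passed at 0.16 (0.00288) and the hypoxia list at −0.08 (0.0402), but without WT replicate 3 their signs turned, to −0.07 (0.0837) and 0.04 (0.345). The ribosomal list passed at 0.09 without WT replicate 3 (2.57e-05), and its mean was 0.01 without WT replicate 1 (0.829). It also passed at 0.10 with the Y-linked covariate (9.06e-07) and at 0.08 without both arrays that stood apart (0.000541). The melanocyte mean ran from −0.05 without WT replicate 1 to 0.09 without WT replicate 3, the macrophage mean from −0.07 without WT replicate 3 to 0.03 without WT replicate 2, and the unfolded protein response mean from 0.01 without WT replicate 2 to 0.06 without WT replicate 1. The erythrocyte mean ran from −0.21 without WT replicate 3 to 0.18 without WT replicate 1.

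Of the control probe sets, those for 18S ribosomal RNA separated the genotypes at the 3' and 5' ends, with 3858 ± 2156 and 7285 ± 3937 in Oa1-/- (SD, n = 3) against 1817 ± 296 and 2838 ± 1049 in WT. The 3' to 5' signals of Actb and Gapdh overlapped between the genotypes. The 3' minus 5' log2 signal of Actb was 0.36 ± 0.08 in WT and 0.32 ± 0.07 in Oa1-/- (SD, n = 3, exact permutation p = 0.6), and that of Gapdh was −0.20 ± 0.16 and −0.28 ± 0.04 (SD, n = 3, exact permutation p = 0.7).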

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

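The tests on the sex of the pools and on single probe sets were chosen after their results had been seen, as were those of scaling, sex mix and tissue for the mesenchyme list and the count of splits for single probe sets. The counts of splits for the lists were planned, but the mesenchyme list was named after its result in the real split was known.

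Control probe sets for 18S ribosomal RNA, which were left out of the model over all probe sets, gave a higher signal in Oa1-/-. The 3' probe set read 1817 ± 296 in WT and 3858 ± 2156 in Oa1-/- (SD, n = 3, exact permutation p = 0.1, the smallest possible), and the 5' probe set read 2838 ± 1049 and 7285 ± 3937 (SD, n = 3, exact permutation p = 0.1). The middle probe set read 1833 and 3790, with overlapping groups. Oa1-/- replicate 1 was highest on all 3, at 6348, 6576 and 11826.

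WT replicate 3 had almost no Y-linked signal. On it, 6622 probe sets as bright as the Y-linked ones had a median log2 difference of −0.04 (−0.0387) from the other WT arrays. All arrays had been scaled to a common target, so this median cannot tell whether the array was dim before scaling. Scaling moves the Y-linked probe sets by the same factor as those 6622, however. The median near that of the other WT arrays therefore argues against dimness as the source of the low Y-linked signal. A pool of the other genotype is argued against by a Gpr143 signal of 246. Such a pool would not by itself have lacked Y-linked signal, since the Oa1-/- arrays had it. A pool without male embryos is a candidate explanation: the smallest gap between this array and the lowest other one was 2.76 on the log2(signal + 16) scale over the 3 genes, where the size of the gap depends on the pseudocount because the low values lie at the background. At even odds, 1.56% of pools of 6 would hold no male, and 9.02% of sets of 6 pools would hold such a pool. No biological explanation tied to the genotype was tested.

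The change of the genes with a lower signal differed between probe sets. For Kantr, Slc25a29 and Dcx, the 95% interval of the brightest other probe set reached at most 16.4% of the named change. The Oa1-/- values of Kantr and Slc25a29 lie near the background, but with pseudocounts of 1 and 64, chosen after seeing the data, that share was at most 14.1% and 22.4%. For Erdr1, Peg3, Dnmt3a and Tfap2b that interval reached at least 52.6%. The genes were grouped by this share after it had been seen. A dimmer Kantr probe set, 1438576_x_at, had a lower mean too, at 73.0 in WT and 24.6 in Oa1-/-. The brightest other probe set alone therefore cannot decide on the whole Kantr transcript. For Slc25a29 the other tested probe sets had log2 changes of 0.01, 0.000647, −0.13 and −0.29, against −1.69. For Dcx the other tested one had 0.29 (SE 0.10), against −1.25. For Slc25a29 and Dcx these values argue against a fall of the whole transcript as large as the named change. A smaller fall stays open for Slc25a29, and a lower amount stays open for Kantr, Erdr1, Peg3, Dnmt3a and Tfap2b. A segment of the X chromosome carried along with the targeted allele may bear on Kantr, which lies 5 measured genes from Gpr143, and cannot be told apart, because 5 of 52 probe sets of genes nearby (9.62%) had a p below 0.05, against 43 of 693 elsewhere on that chromosome (6.20%, one-sided Fisher's exact p = 0.237). A change in transcript form with the genotype, and a strain variant under the probes, stay open and untested.

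For the lower mesenchyme list, the mean log2 change, −0.15, was −0.119 with median centring and −0.125 with the Y-linked covariate. The list stayed past the threshold of camera with the preset correlation in both, and with quantile normalization. Centring shifts all genes of an array alike, while camera compares a list with the other genes, so it cannot decide on the authors' scaling. The Y-linked score mainly sets apart WT replicate 3. Without that array the brightest Xist probe set still had a log2 change of −0.33, so the sex mix of the pools stays open. Less non-retinal tissue in the Oa1-/- pools could contribute and stays open: the mean score of 5 other non-retinal lists differed by −0.00611 (SE 0.123), too wide an error to decide. Of the 10 splits of the 6 arrays, 1 gave a camera p as small, the real one (2.99e-06), and the smallest of the others was 5.73e-05, for the split that put WT replicate 1 with Oa1-/- replicates 2 and 3. The splits are too few for a share under 0.05, and an effect of the genotype on this tissue stays open.

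The same limit holds for the counts. The real split gave 1111 probe sets at an unadjusted p below 0.05, 5 of 10 splits gave as many, and the highest other gave 2409. For lists the real count was 4, 9 of 10 splits gave as many, and the highest other gave 14. The splits are too few for a share under 0.05. The list counts rest on the preset correlation, and what lies behind the higher counts of other splits was not tested.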

How the results depend on the processing

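The Y-linked covariate and the fit without both arrays that stood apart (WT replicate 3 and Oa1-/- replicate 1) were chosen after seeing the data. The number of probe sets past the threshold was 0 in limma under all alternatives except 2 with median centring (Gpr143 and Kantr, adjusted p = 0.000635) and 2 with array weights (Kantr, 0.0105, and Slc25a29, 0.0192). The prior degrees of freedom were 15.3 with centring against 4.38; the cause of either change was not tested. Probe sets at an unadjusted p below 0.05 numbered 3090 with array weights, 1968 with no filter (of 45037) and 771 with centring, against 1111. They numbered 1527 without both arrays that stood apart and 1553 with the covariate.

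The number of lists past the threshold, 4, was 2 with quantile normalization, 0 with an estimated correlation, 0 with fry and 7 with the covariate, and 6 without both arrays that stood apart. Leaving out 1 array gave 3 to 8 lists: 7 without WT replicate 1, 8 without WT replicate 2, 7 without WT replicate 3 and 3 without Oa1-/- replicate 1. The muscle list, at 0.14, reversed to −0.28 (−0.276) with array weights, and with 1 array left out it ran from −0.213 (without WT replicate 1) to 0.417. It was 0.496 with the covariate. With 1 array left out the lens list, at 0.08, ran from −0.129 (without WT replicate 1) to 0.187, and it was 0.211 with the covariate; the cause was not tested. The mesenchyme list passed under all alternatives but an estimated correlation (adjusted p = 0.604) and fry (0.527), with means from −0.184 to −0.119. Of 504 values for the 24 other lists, 66 had another direction by camera or fry, which can differ from the sign of the mean, and 25 passed.

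Gpr143 kept an unadjusted p below 0.05 throughout, from −3.64 (pseudocount 1) to −1.85 (pseudocount 64), and from −3.09 to −2.43 with 1 array left out. Of 830 values for the 47 other named probe sets, 3 passed and 1 changed sign (Uty, with the covariate made partly from it). With 1 array left out, 17 of the 47 moved by over 1.5 times. At the 70th percentile filter 12 of them had no value. The Actb 3' to 5' difference ran from −0.0738 to 0.00234 and the Gapdh difference from −0.128 to 0.0116 with 1 array left out.

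The replicate numbers did not pair the samples: deviations of arrays with the same number had correlations of −0.294, 0.152 and −0.248, and not every array correlated best with its own number. With the replicate number as a block, 0 probe sets and 4 lists passed, 888 probe sets had an unadjusted p below 0.05, and Gpr143 had a log2 change of −2.82. Signals near the bacterial controls, at 22.1 to 39.3, limit what the lower values of Gpr143, Kantr and Slc25a29, and the Y-linked values on WT replicate 3, can show.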

Other observations

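Some single genes of lists that did not pass had small unadjusted p values, and 0 of them passed the adjustment in limma. They were chosen after their values were seen, and name no theme, since the lists they come from did not pass (among them axon guidance, camera adjusted p = 0.787, and cell cycle, 0.800). Shh, the signal made by retinal ganglion cells that acts on progenitors and the optic nerve, read 505 ± 80.5 in WT and 718 ± 53.1 in Oa1-/- (log2 change 0.51, adjusted p = 0.985). The cell adhesion gene Chl1 had a log2 change of 0.60, while the ephrins Efnb1 and Efna5 had −0.30 and −0.23. The eye transcription factor Pax6 had a log2 change of 0.16. Prox1, which marks horizontal cells and lens fibres, read 467 ± 51.3 and 305 ± 78.0 (log2 change −0.61).

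Among genes of the cell cycle, Hmgb2 had a log2 change of 0.30 and Pcna one of 0.20. The CDK inhibitor Cdkn2d had one of 0.24 and the cyclin Ccnd2 one of −0.23. The cartilage genes Matn4 and Col2a1 had log2 changes of −0.31 and −0.31. All of these had an adjusted p of 0.985.

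A hypothesis of wider change among imprinted genes, from Nnat and Peg3, was tested with its prediction written before the result was seen, on a list of 44 imprinted genes that left out Nnat, Peg3 and Snrpn, whose values had been seen. Of these, 34 were measured, 18 higher and 16 lower, and 0 had an unadjusted p below 0.05. Their mean absolute moderated t, 0.819, lay at percentile 43.5 of 10000 lists matched on mean signal, which had a median of 0.836 and an SD of 0.114. The prediction against the hypothesis was a value below that median, which was met. It was met by less than 1 SD of the matched lists, a condition applied only after the value had been seen, so the test gave no support for a wider change and did not exclude one.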
